A study of Mus musculus with 8 samples.

How the data were processed

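RNA was sequenced from mouse nTreg cells (CD4-positive, reporter-positive cells sorted from spleen and lymph nodes of Cas9-expressing Foxp3 reporter mice and cultured), with a control or a Foxp3 guide RNA, mock-treated (0 h) or stimulated with antibodies to CD3 and CD28 (3 h). Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.3, aligned to the mouse genome (mm10, GRCm38) with STAR 2.7.9a and quantified with RSEM 1.3.1. The authors deposited expected count values per gene, which were rounded to whole numbers for the count models. The deposited TPM values per gene, also from the authors, were used only as an alternative scale. Columns were matched to libraries by the deposited labels, with 0 columns left unmatched. Gene identifiers were looked up in GENCODE M21 on GRCm38: 55180 of 55665 matched with their version and 55480 without it. The labels do not name the annotation release that was used.

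The 8 libraries formed 4 groups of 2, by guide and time. Total expected counts were 38729009 and 42698042 (control guide, 0 h), 48626432 and 45518491 (control guide, 3 h), 66804803 and 64135431 (Foxp3 guide, 0 h) and 55865290 and 94807362 (Foxp3 guide, 3 h). Replicates were checked for duplication: the chi-square per gene between the libraries of a group was 4.90 to 8.18. The 5 comparisons were the guide effect at 0 h, the guide effect at 3 h, the TCR effect with each guide, and the difference between the TCR effects. These comparisons, the tests, the gene lists, the rule for naming genes and the alternatives, except where stated, were chosen before the data were examined.

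Genes were filtered with edgeR's filterByExpr, which kept 16642, and scaled by TMM. A quasi-likelihood model with robust dispersion (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3) was fitted to all 8 libraries with 1 mean per group, leaving 4 residual degrees of freedom and a median prior of 19.1; the common biological coefficient of variation was 3.41%. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p below 0.05. CPM values use the TMM-scaled library size and are given as mean ± SD (n = 2); log2 changes are given with their SE. For a group at 0 counts a fold is a lower bound against 3 counts over the group. With 1 to 3 counts a ratio is given with a 95% counting interval. These bounds and intervals cover counting error only.

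Gene lists, 28 in number, were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, with fry as a further alternative. They were Treg signature, conventional T cell genes, effector cytokines, helper lineage factors, immediate early genes, NF-kappaB targets, inhibitory receptors, costimulatory genes, homing genes, chemokines, IL-2 and STAT5 targets, cytotoxic genes, interferon-stimulated genes, ribosome biogenesis, glycolysis, cholesterol, respiratory chain, amino acid stress, cell cycle, p53 targets, BCL-2 family and other apoptosis regulators, Foxp3 cofactors, and markers of B, CD8, NK, myeloid, erythroid and stromal cells. Some genes stand in more than 1 list. Named genes were Foxp3, then the 10 largest rises and 10 largest falls of each comparison among called genes with a mean log2 CPM of at least 3, and then the list members with the largest changes past the threshold. The mean log2 CPM was taken over all 8 libraries, so a gene can pass with few counts in both groups compared. Numbered gene models and antigen receptor segments were counted but not named among the largest changes. For the first 4 comparisons the rule also required both libraries of one group to lie above both of the other.

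The pipeline was tested on simulated data with known changes. Each fold was given to 50 of 16642 genes, drawn from those with enough counts, in random directions. So few changed genes cannot test how scaling behaves when a large share of genes changes. For the guide effect at 0 h it recovered 52%, 72%, 96% and 100% of genes changed 1.2-, 1.5-, 2- and 4-fold, and for the interaction 32%, 56%, 76% and 98%. False calls were 11 of 171 and 4 of 135. Alternatives were median-ratio (RLE) and upper-quartile scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM+1) with and without the gene filter and on log2(TPM+0.1), no filter, at least 1 CPM in all libraries, only the 4 libraries compared, replicate number as a block, an adjusted p of 0.01, a 2-fold minimum, glmTreat against 1.2-fold, dispersion without robust fitting, and each library left out in turn. Thinning all libraries to the smallest total and a 2-fold test of the interaction were added after the data were seen. Groups of 2 allow neither a test for outlying libraries nor a count of regrouped samples. All libraries were kept.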

Results

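Stranded RNA-seq libraries were made from mouse natural regulatory T (nTreg) cells, CD4 T cells that carried a green fluorescent reporter of Foxp3 together with Cas9 and were sorted from spleen and lymph nodes before culture. The cells received a non-targeting control guide RNA or a guide against Foxp3, the transcription factor that specifies Treg identity. Each culture was either mock-treated with buffer (0 h) or restimulated through the T cell receptor (TCR) with antibodies against CD3 and CD28 for 3 h. The 4 groups held 2 libraries each, 8 in all. Library totals were 38729009 and 42698042 expected counts for the control guide at 0 h and 48626432 and 45518491 at 3 h. Foxp3-guide libraries were deeper, with 66804803 and 64135431 at 0 h and 55865290 and 94807362 at 3 h. Ribosomal protein genes took 5.20% to 5.6% of the counts in control-guide libraries and 6.29% to 7.21% in Foxp3-guide libraries. Mitochondrial transcripts took 1.87% to 2.28% across the 8 libraries. The first principal component, with 78.7% of the variance, parted 0 h from 3 h, and the second, with 14.8%, parted the guides. Of 55665 annotated genes, 16642 had enough counts to test.

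Foxp3 itself (ENSMUSG00000039521.13; GRCm38 chromosome X, 7573644 to 7595245, plus strand, protein coding) was measured first, since the guide targets it. Its level was 769.9 ± 8.51 CPM (SD, n = 2) with the control guide at 0 h and 88.0 ± 0.621 CPM with the Foxp3 guide. After 3 h of TCR stimulation it was 676.1 ± 3.82 and 73.9 ± 3.05 CPM. The transcript fell by 3.13 on the log2 scale (SE 0.041) at 0 h and by 3.19 (SE 0.04) at 3 h. The difference between these guide effects was -0.07 with an adjusted p of 0.38, so none was detected. TCR stimulation alone changed Foxp3 by -0.19 ± 0.04 with the control guide and -0.25 ± 0.04 with the Foxp3 guide. The fall was larger in TPM. With the control guide the libraries stood at 485.76 and 501.26 TPM at 0 h and at 337.14 and 329.81 at 3 h. With the Foxp3 guide they stood at 44.01 and 44.41 TPM at 0 h and at 30.72 and 27.89 at 3 h. The size of this fall thus depends on scaling.

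**Figure D1:**
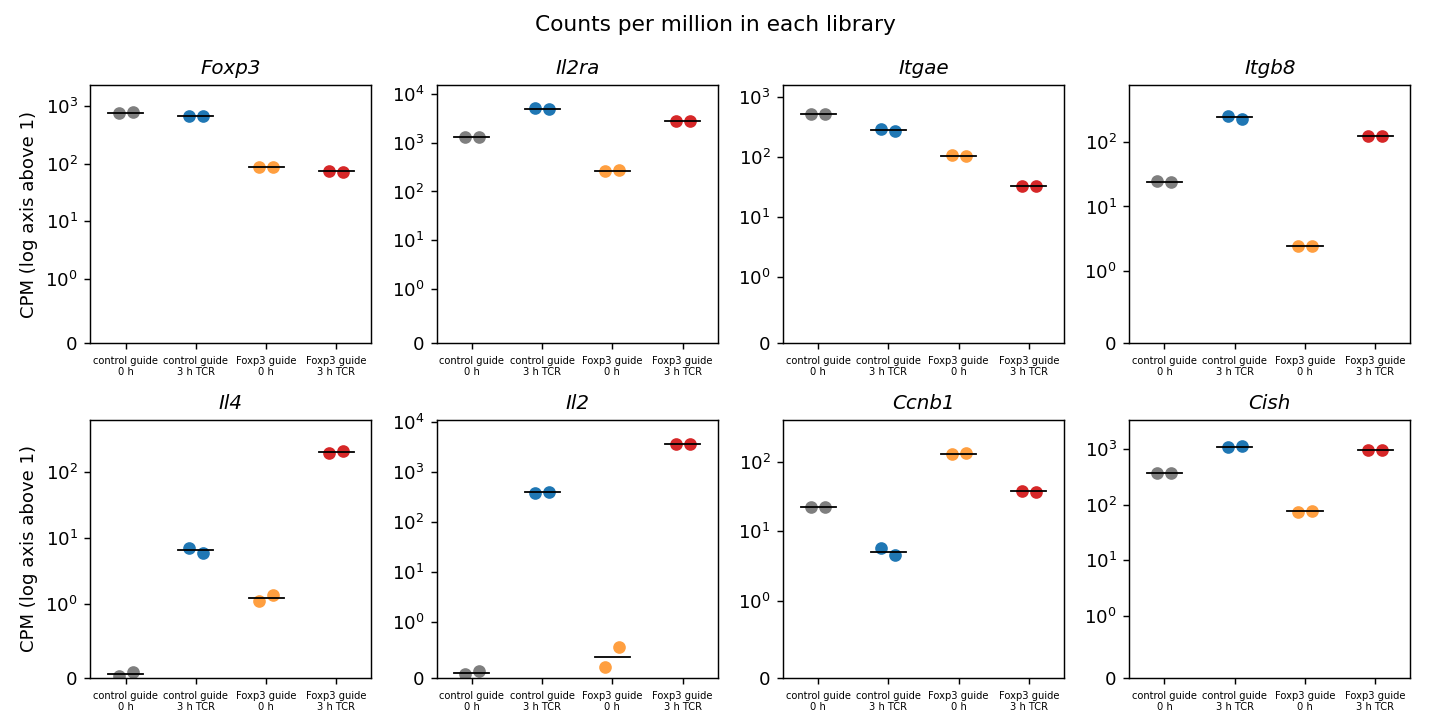
CPM of 8 genes in each of the 8 libraries, on an axis that is logarithmic above 1 and linear below; points are libraries and bars are group means. Foxp3 lay near 769.9 and 676.1 CPM with the control guide and near 88.0 and 73.9 CPM with the Foxp3 guide.

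The first comparison asked what loss of Foxp3 changed in unstimulated cells. Foxp3-guide cells had lower levels of Treg signature genes and of IL-2 and STAT5 target genes, and higher levels of cell cycle genes and of genes typical of conventional naive CD4 T cells. Among the 30 Treg signature genes, 24 fell, 3 rose and 3 did not pass the test; the count adjusted over the list alone was 27. Itgb8, the integrin subunit that activates latent TGF-beta (ENSMUSG00000025321.14; chromosome 12, 119158022 to 119238802), fell from 24.1 ± 0.393 to 2.45 ± 0.00656 CPM (log2 change -3.29 ± 0.086 SE). The surface receptor gene Cd83 changed by -3.28 ± 0.1, the costimulatory receptor gene Tnfrsf9 by -2.99 ± 0.05 and Gpr83 by -2.78 ± 0.06. Il2ra, the high-affinity IL-2 receptor chain (ENSMUSG00000026770.5; chromosome 2, 11642807 to 11693193), went from 1298 ± 18.5 to 265.9 ± 5.83 CPM. The signature's median log2 change was -0.80 (camera adjusted p = 1.3e-25; adjusted p = 0.0037 with an estimated correlation).

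IL-2 and STAT5 targets moved with the signature in unstimulated cells. All 12 members passed: 11 fell and 1, the granzyme gene Gzmb, rose by 1.58 ± 0.05. Cish, a STAT5-induced inhibitor of cytokine signalling (ENSMUSG00000032578.7; chromosome 9, 107296026 to 107302784), fell by 2.32 ± 0.04, Socs1 by 1.99 ± 0.08 and the cyclin gene Ccnd2 by 1.66 ± 0.04. The median was -1.22 (camera adjusted p = 5.5e-14; adjusted p = 0.011 with an estimated correlation). Stat5a, listed among the Foxp3 cofactors, fell by 1.46 ± 0.04.

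All 20 cell cycle genes rose in unstimulated Foxp3-guide cells, with a median log2 change of 2.25 (camera adjusted p = 2.5e-66; adjusted p = 0.0012 with an estimated correlation). The mitotic cyclin gene Ccnb1 (ENSMUSG00000041431.16; chromosome 13, 100778650 to 100786570) rose from 22.2 ± 0.406 to 130.1 ± 4.3 CPM, a log2 change of 2.55 ± 0.05. Ccna2 rose by 2.53 ± 0.04, Ccnb2 by 2.49 ± 0.06 and the mitotic kinase gene Cdk1 by 2.46 ± 0.05. Of the 15 conventional T cell genes, 10 rose, 3 fell and 2 did not pass, and 13 passed when adjusted over the list alone. Tcf7, a transcription factor of naive and memory T cells (ENSMUSG00000000782.15; chromosome 11, 52252371 to 52283014), rose from 180.1 ± 0.921 to 941.5 ± 8.08 CPM. Pde3b, a cyclic nucleotide phosphodiesterase that Foxp3 represses, rose by 3.31 ± 0.059, Dapl1 by 2.04 ± 0.33 and the costimulatory ligand gene Cd40lg by 1.17 ± 0.09. The list median was 0.86 (camera adjusted p = 1.7e-06; adjusted p = 0.044 with an estimated correlation).

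Outside these groups, the matrix protein gene Svep1 (ENSMUSG00000028369.15; chromosome 4, 58042442 to 58206859) had the largest fall among the named genes, from 32.5 ± 0.889 to 0.428 ± 0.0287 CPM, a log2 change of -6.24 ± 0.17. Gad1, a glutamate decarboxylase, changed by -5.27 ± 0.16 and Hepacam2, an immunoglobulin-family adhesion gene (ENSMUSG00000044156.14; chromosome 6, 3457096 to 3498298), by -5.24 ± 0.11. Frmd5, Mir155hg (the host transcript of miR-155) and the activin receptor gene Acvr1c changed by -3.14 ± 0.087, -3.05 ± 0.42 and -2.99 ± 0.082. Utf1 had 1 count with the Foxp3 guide and 8 with the control guide, a log2 ratio of -3.58 with a counting interval of -9.05 to -0.68; without Foxp3-guide 0 h replicate 1 its adjusted p was 0.0672. Il4, the type 2 helper cytokine gene (ENSMUSG00000000869.12; chromosome 11, 53602982 to 53618669), led the rises among genes with a mean log2 CPM of at least 3, by 4.50 ± 0.67 on 176 against 5 counts. That mean is taken over all 8 libraries, and Il4 had 26457 counts with the Foxp3 guide at 3 h. The lipid flippase gene Atp8b4 rose by 4.19 ± 0.18, the monoacylglycerol lipase gene Mgll by 3.96 ± 0.2, the mTORC2-associated gene Prr5l by 3.84 ± 0.071 and Phldb1 by 3.27 ± 0.072. Fbln1, the alpha globin gene Hba-a1, the TNF-family ligand gene Tnfsf14 and the ubiquitin ligase gene Rnf144a rose by 3.15 ± 0.13, 3 ± 0.058, 2.96 ± 0.2 and 2.95 ± 0.094. Reads of Hba-a1 and its near-identical copy Hba-a2 cannot be assigned with certainty.

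Several other lists were lower in unstimulated Foxp3-guide cells under the preset correlation and lost that call when the correlation was estimated. NF-kappaB targets had 11 members lower and 2 higher of 15, led by Bcl3 at -1.53 ± 0.06 and, upward, Bcl2a1d at 2.38 ± 0.19 (camera adjusted p = 0.00035; adjusted p = 0.079 with an estimated correlation). Bcl2a1b and Bcl2a1d are close paralogs whose reads are hard to separate. Among 22 immediate early genes 14 fell and 2 rose, including Myc at -2.39 ± 0.05 and Jun at -1.82 ± 0.04, while the phosphatase gene Dusp6 rose by 1.98 ± 0.08 (camera adjusted p = 0.0031; adjusted p = 0.45 with an estimated correlation). Costimulatory genes had 8 lower and 3 higher of 12, with Tnfrsf4 at -1.15 ± 0.04 (camera adjusted p = 0.00092; adjusted p = 0.13 with an estimated correlation). Respiratory chain subunits had 16 of 17 members higher and none lower, led by Cox5a at 0.70 ± 0.05, with a median of 0.31 that came to 0.01 on the TPM scale (camera adjusted p = 0.016; adjusted p = 0.63 with an estimated correlation).

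No camera call was made at 0 h for the remaining functional lists. Homing genes had 6 higher and 9 lower of 17. Among them were Ccr9 at -4.30 ± 0.46, Cxcr5 at -2.87 ± 0.11, Ccr6 at -2.77 ± 0.12 and Itgae (integrin subunit CD103) at -2.31 ± 0.04. Cytotoxic genes had 4 higher and 5 lower of 9 measured, with Prf1 (perforin) at -2.43 ± 0.15 and Nkg7 at 1.85 ± 0.1. Inhibitory receptors had 3 higher and 4 lower of 10, interferon-stimulated genes 5 and 6 of 14, and ribosome biogenesis genes 4 and 11 of 18. Glycolysis genes had 10 higher and 4 lower of 16, with Pgk1 at 1.42 ± 0.04 and Slc2a3, a glucose transporter, at -1.59 ± 0.04. Cholesterol genes had 11 higher and 1 lower of 16 and amino acid stress genes 9 and 2 of 16, but their medians of 0.24 and 0.17 turned to -0.03 and -0.10 on the log2(TPM+1) scale. Targets of p53 had 10 higher and 2 lower of 14, BCL-2 family genes 7 and 4 of 12, and Foxp3 cofactors 9 and 11 of 23. The medians of the p53 targets, BCL-2 family and glycolysis genes, 0.31, 0.31 and 0.3, came to 0.02, 0.02 and 0.01 on the log2(TPM+1) scale. Effector cytokine genes had 2 higher, 2 lower and 10 not past of 14, with a median of 0.02 that was 0 under RLE, upper-quartile and DESeq2 scaling and 0.01 on the log2(TPM+1) scale, and a mean of 0.91. Helper lineage factors had 4 higher and 5 lower of 13, with Tbx21 at 1.86 ± 0.13, and their median of 0.01 turned negative under every other scaling tried. Chemokines had 1 higher and 1 lower of 9. The mean of the cytokine, helper factor, chemokine and cytotoxic lists was above 0 while the direction of the camera test was down, and for the cofactors a median of -0.01 stood against a mean of 0.07.

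Markers of other cell types moved with the guide at 0 h as follows. B cell markers had 3 lower and 1 higher of 5 measured: Ighm fell from 926.3 ± 1.59 to 250.2 ± 2.19 CPM, a log2 change of -1.89 ± 0.04, Ighd fell by 2.13 ± 0.1 and Ebf1 by 1.86 ± 0.18 (camera adjusted p = 0.0011; adjusted p = 0.1 with an estimated correlation). Erythroid markers had 2 higher of 3, both alpha globin genes (camera adjusted p = 0.00092; adjusted p = 0.13 with an estimated correlation). Klrb1c, an NK receptor gene, had 147 counts with the Foxp3 guide and 3 with the control guide, a log2 ratio of 5.04 with a counting interval of 3.46 to 7.33. Natural killer markers had 2 higher of 2, myeloid markers 2 higher and 4 not past of 6, stromal markers 2 lower of 3, and neither CD8 marker passed; none of these 4 lists had a camera call. The myeloid median of 0.78 turned to -0.10 on the log2(TPM+1) scale, and that of the CD8 markers went from 0.25 to -0.08. The NK marker Eomes rose by 0.32 ± 0.14 and turned slightly negative on that scale.

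Across all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 10539 of 16642 genes at 0 h, 5694 higher and 4845 lower. At 2-fold or more there were 2586, 1532 higher and 1054 lower. The balance depends on scaling: 54% of calls were higher under TMM scaling, 44.8% under upper-quartile scaling and 27.9% on the log2(TPM+1) scale, where the median of all genes went from 0.023 to -0.152 (-0.217 with a pseudocount of 0.1). Among genes changed at least 2-fold the share that was higher went from 59.2% to 45.6% on that scale. Each p-value measures the spread between these libraries, which may be technical, because the labels do not say that the libraries came from separate cultures or animals.

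The second comparison asked the same question 3 h after TCR stimulation. Effector cytokine transcripts were then higher in Foxp3-guide cells, cell cycle genes were again higher, and Treg signature genes were again lower. Of 14 cytokine genes 13 rose and 1 did not pass; all 14 passed when adjusted over the list alone. Il4 rose from 6.63 ± 0.828 to 199.9 ± 9.6 CPM (log2 change 4.91 ± 0.078 SE) and its neighbour Il13 (ENSMUSG00000020383.1; chromosome 11, 53631324 to 53634702) from 17.4 ± 0.643 to 489.1 ± 12.4 CPM (4.81 ± 0.051). Il5, the third cytokine of the type 2 locus, rose by 4.15 ± 0.15. Il2, the T cell growth factor (ENSMUSG00000027720.7; chromosome 3, 37120523 to 37125959), rose from 395.4 ± 4.39 to 3693 ± 108 CPM, a log2 change of 3.22 ± 0.066. The list median was 1.84 (camera adjusted p = 5.7e-43; adjusted p = 0.026 with an estimated correlation).

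In the Treg signature 21 genes fell, 5 rose and 4 did not pass at 3 h, and 28 passed when adjusted over the list alone. Itgae (ENSMUSG00000005947.11; chromosome 11, 73090583 to 73147446) went from 281.3 ± 12.2 to 32.5 ± 0.0951 CPM, a log2 change of -3.11 ± 0.04. Lrrc32, which anchors latent TGF-beta at the Treg surface, changed by -2.34 ± 0.04, Klrg1 by -2.64 ± 0.58 and Gpr83 by -1.88 ± 0.05. Ctla4, counted among the inhibitory receptors, changed by -1.63 ± 0.04. The signature median was -0.84 (camera adjusted p = 4.1e-19; adjusted p = 0.012 with an estimated correlation). All 20 cell cycle genes rose, Ccnb1 by 2.87 ± 0.08, Ccna2 by 2.66 ± 0.06 and the kinase genes Aurkb and Bub1 by 2.62 ± 0.08 and 2.58 ± 0.09, with a median of 2.38 (camera adjusted p = 2.3e-55; adjusted p = 0.012 with an estimated correlation).

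With the same minimum level, other genes with the largest changes at 3 h included several that had also led at 0 h. Hepacam2, Svep1 and Gad1 changed by -6.28 ± 0.36, -5.82 ± 0.17 and -4.14 ± 0.1, and Frmd5 by -3.38 ± 0.2. Kctd12b changed by -4.76 ± 0.44 on 8 against 149 counts, Apol9b by -4.66 ± 0.11, the transcription factor gene Myb by -3.55 ± 0.066, the urea transporter gene Slc14a1 by -3.43 ± 0.081 and the ubiquitin ligase gene Nedd4 by -3.29 ± 0.099. Hmgb1-ps8, a pseudogene whose reads may come from its parent gene family, changed by -3.35 ± 0.19. Upward, Atp8b4 changed by 4.33 ± 0.14, the thrombin receptor family gene F2rl2 by 3.53 ± 0.098, the cytokine gene Il31 by 3.46 ± 0.058 and the galectin gene Lgals3 by 3.21 ± 0.047. The leukotriene receptor gene Cysltr1 rose by 3.15 ± 0.13 and Fbln1 by 3.13 ± 0.17. Hba-a1 rose by 3.47 ± 0.063.

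Another 6 functional lists had a camera call at 3 h that was lost with an estimated correlation. Homing genes had 12 lower and 5 higher of 17: Klf2, the transcription factor that maintains lymphocyte egress receptors, changed by -2.90 ± 0.09, Cxcr5 by -2.40 ± 0.12 and Ccr2 by 2.30 ± 0.05 (camera adjusted p = 0.00017; adjusted p = 0.057 with an estimated correlation). Cholesterol synthesis genes had 14 higher and 1 lower of 16, led by Fdps at 1.43 ± 0.06 (camera adjusted p = 0.00021; adjusted p = 0.057 with an estimated correlation). Amino acid stress genes had 12 higher and 1 lower of 16, among them Chac1 at 3.27 ± 0.25 and Trib3 at 2.67 ± 0.12 (camera adjusted p = 1.1e-05; adjusted p = 0.15 with an estimated correlation). Inhibitory receptors had 7 higher and 2 lower of 10, with Cd160 at 2.88 ± 0.06 and Havcr2 (TIM-3) at 1.37 ± 0.04 (camera adjusted p = 0.0081; adjusted p = 0.15 with an estimated correlation). Cytotoxic genes had 6 higher and 3 lower of 9, with Serpinb6b at 2.41 ± 0.05 and Gzma at 2.10 ± 0.16 (camera adjusted p = 0.0081; adjusted p = 0.18 with an estimated correlation). BCL-2 family genes, with 7 higher and 2 lower of 12 and Bcl2l11 (BIM) at 1.46 ± 0.04, followed the same course, and their median of 0.15 turned to -0.06 on the TPM scale (camera adjusted p = 0.014; adjusted p = 0.29 with an estimated correlation).

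Among lists without a call at 3 h, IL-2 and STAT5 targets had 8 lower and 3 higher of 12 with a median of -0.29, Socs2 at -1.09 ± 0.04 and Gzmb at 1.28 ± 0.04. Conventional T cell genes had 7 higher and 7 lower of 15, with Cd40lg at 2.22 ± 0.04 and Themis at 2.06 ± 0.05; their median was -0.02 and their mean 0.36. Immediate early genes had 13 lower and 3 higher of 22, led by Dusp6 at 2.34 ± 0.04 and Zfp36 at -1.72 ± 0.04, and NF-kappaB targets 9 lower and 6 higher of 15, led by Icam1 at -1.57 ± 0.04. Costimulatory genes had 5 higher and 5 lower of 12; Tnfsf8, the CD30 ligand, rose by 2.83 ± 0.04 and Tnfrsf18 (GITR) changed by -1.30 ± 0.04, and the median of 0.01 turned to -0.01 under upper-quartile scaling and -0.20 on the TPM scale. Helper lineage factors had 5 higher and 8 lower of 13, with Prdm1 (BLIMP-1) at -1.91 ± 0.08. Chemokines had 5 higher and 3 lower of 9 and interferon-stimulated genes 5 and 6 of 14. Ribosome biogenesis genes had 14 higher and 1 lower of 18, glycolysis genes 9 and 6 of 16, respiratory chain genes 13 and 1 of 17, p53 targets 8 and 3 of 14, and Foxp3 cofactors 12 and 6 of 23. The medians of these 5 lists lay between 0.13 and 0.17 and turned to between -0.11 and -0.04 on the TPM scale. Of the markers of other cells, both alpha globin genes rose again (erythroid list: camera adjusted p = 2.1e-05; adjusted p = 0.057 with an estimated correlation), and Ighm fell by 1.66 ± 0.04 with 3 of 5 B cell markers lower and none higher (camera adjusted p = 0.027; adjusted p = 0.18 with an estimated correlation). Myeloid markers had 3 higher and 2 lower of 6, with Itgam at 2.26 ± 0.19, stromal markers 2 higher and 1 lower of 3, CD8 markers 2 higher of 2, and NK markers 1 lower of 2, all without a call. The NK median of 0.02 turned to -0.50 on the log2(TPM+1) scale. Medians and means differed in sign for glycolysis (mean -0.03), interferon-stimulated (median -0.10, mean 0.16) and stromal lists (median 0.45, mean -0.19), and the camera direction was opposite to the median for the glycolysis, conventional T cell, helper factor and NK lists.

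**Figure D2:**
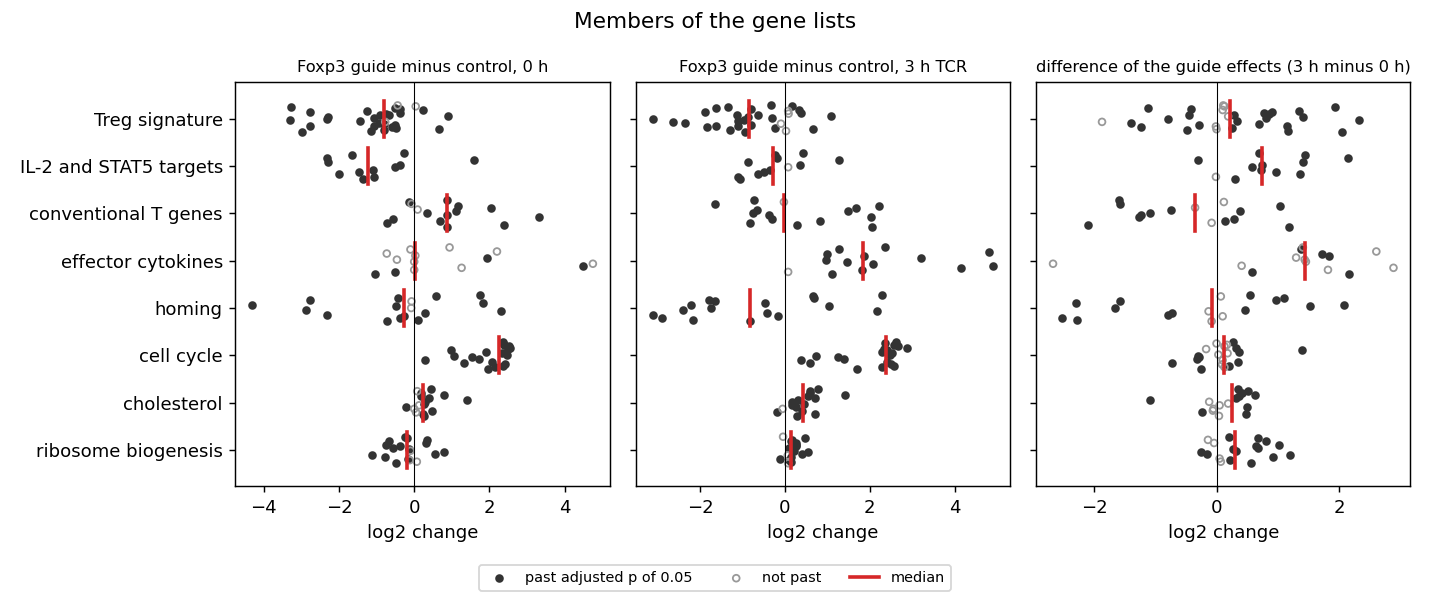
Log2 changes of the members of 8 gene lists for the guide effect at 0 h, the guide effect at 3 h and the difference between them; filled points passed the test over all genes, open points did not, and red bars are list medians. Cell cycle medians were 2.25 at 0 h and 2.38 at 3 h, and effector cytokine medians 0.02 and 1.84, while on the log2(TPM+1) scale the median of cholesterol genes at 0 h turned to -0.03, that of ribosome biogenesis genes at 3 h to -0.05 and that of the homing differences to 0.06.

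The test called 10231 genes at 3 h, 5104 higher and 5127 lower, of which 1283 higher and 1477 lower passed 2-fold. On the log2(TPM+1) scale 27.5% of calls were higher against 49.9% under TMM scaling, and the median of all genes moved from -0.009 to -0.118. Without Foxp3-guide 3 h replicate 1 or 2 it moved the other way, to 0.053 or 0.025. At 2-fold or more the share that was higher was 46.5% under TMM scaling and 36.1% on the log2(TPM+0.1) scale. Guide effects at 0 h and 3 h, which share no library, correlated across genes with Pearson's r = 0.556 and Spearman's rho = 0.542; genes are not independent replicates. Of 7575 genes called at both times, 82.3% had the same direction: 3253 were higher at both and 2978 lower at both, where independent lists would give 1746 and 1493. Another 1344 had opposite directions.

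The third comparison asked how control-guide Treg cells responded to 3 h of TCR stimulation. Transcripts of cytokines, chemokines, immediate early factors, NF-kappaB targets and ribosome biogenesis genes rose, while most cell cycle genes fell. The chemokine gene Ccl1 and the cytokine genes Il3 and Il31 were at 0 counts at 0 h, so only lower bounds can be given against 3 counts over the group. Il3 was at least 14200-fold higher, Ccl1 at least 8160-fold and Il31 at least 471-fold; Idi2, also at 0 counts, was at least 527-fold higher. Ccl4, Xcl1 and Cxcl2 had 2, 2 and 1 counts at 0 h, with log2 ratios of 15.51 (counting interval 13.66 to 18.55), 14.98 (13.13 to 18.02) and 12.76 (10.28 to 18.06). Ccl3 rose by 13.41 ± 0.6, Il2 by 11.98 ± 0.62 and Egr2, a TCR-induced transcription factor gene, by 11.42 ± 0.23.

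All 14 effector cytokine genes rose with the control guide. Il13 had 1 count at 0 h and 1521 at 3 h, a log2 ratio of 10.67 with a counting interval of 8.19 to 15.98, and Csf2 (GM-CSF) rose by 10.22 ± 0.5. The cytokine median was 7.12, also with genes at 0 counts set to their bounds (camera adjusted p = 6.7e-19; adjusted p = 0.033 with an estimated correlation). All 9 chemokines rose, with a median of 8.55 on either basis (camera adjusted p = 1.7e-10; adjusted p = 0.046 with an estimated correlation). Of 22 immediate early genes 21 rose and 1 fell; Nr4a3 rose by 8.69 ± 0.07 and Atf3 by 8.23 ± 0.23, and Fosl1 went from 3 to 8078 counts (camera adjusted p = 8e-35; adjusted p = 0.018 with an estimated correlation). All 15 NF-kappaB targets rose, among them Nfkbid by 4.75 ± 0.05 and Nfkbiz by 3.61 ± 0.04 (camera adjusted p = 3.5e-20; adjusted p = 0.018 with an estimated correlation). All 18 ribosome biogenesis genes rose, led by Gnl3 at 4.6 ± 0.05 and Rrp12 at 4.56 ± 0.06 (camera adjusted p = 1e-35; adjusted p = 0.018 with an estimated correlation).

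Helper lineage factors rose in 11 of 13 cases, with Zeb2 at 9.05 ± 0.38, Tbx21 (T-bet) at 8.25 ± 0.12 and Irf4 at 4.83 ± 0.04 (camera adjusted p = 5.7e-09; adjusted p = 0.021 with an estimated correlation). Inhibitory receptors rose in 9 of 10 cases, led by Havcr2 at 7.20 ± 0.18 and Cd160 at 5.16 ± 0.21 (camera adjusted p = 3.7e-08; adjusted p = 0.024 with an estimated correlation). Costimulatory genes had 9 higher and 3 lower of 12, with Tnfsf14 at 10.32 ± 0.19 and Tnfsf11 (RANKL) at 6.03 ± 0.07 (camera adjusted p = 5.7e-09; adjusted p = 0.033 with an estimated correlation). Treg signature genes had 18 higher and 11 lower of 30, including Areg at 8.75 ± 0.4, Il10 at 5.87 ± 0.08 and Cd83 at 5.01 ± 0.05 (camera adjusted p = 5.7e-05; adjusted p = 0.033 with an estimated correlation). IL-2 and STAT5 targets had 8 higher and 3 lower of 12, with Lif at 6.75 ± 0.06 and Lta at 4.48 ± 0.05 (camera adjusted p = 5.7e-05; adjusted p = 0.035 with an estimated correlation). Cell cycle genes had 16 lower and 1 higher of 20, with Aurkb at -2.75 ± 0.08 and Ccnb2 at -2.66 ± 0.1 (camera adjusted p = 2.1e-06; adjusted p = 0.046 with an estimated correlation).

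Homing genes had 11 lower and 5 higher of 17; S1pr1, the lymphocyte egress receptor, changed by -4.33 ± 0.04, Gpr15 by -3.71 ± 0.1 and Klf2 by -3.70 ± 0.05, while Ccr8 rose by 3.94 ± 0.05 (camera adjusted p = 0.00025; adjusted p = 0.07 with an estimated correlation). Conventional T cell genes had 11 lower and 3 higher of 15, with Tcf7 at -2.63 ± 0.04 and Cd40lg at 5.36 ± 0.08 (camera adjusted p = 0.0047; adjusted p = 0.081 with an estimated correlation). Glycolysis genes had 14 higher and 2 lower of 16, led by Hk2 at 5.42 ± 0.07 (camera adjusted p = 1.8e-07; adjusted p = 0.1 with an estimated correlation), and amino acid stress genes 11 and 4 of 16, led by Slc7a1 at 4.28 ± 0.05 (camera adjusted p = 1.5e-05; adjusted p = 0.065 with an estimated correlation). Cytotoxic genes (7 higher, 2 lower of 9), cholesterol genes (10 and 5 of 16), respiratory chain genes (14 and 2 of 17), BCL-2 family genes (6 and 4 of 12, with Bcl2l1, which encodes BCL-XL, at 5.21 ± 0.05) and B cell markers (1 and 4 of 5, with Ighm at -3.39 ± 0.04) also had calls under the preset correlation. Their adjusted p values with an estimated correlation were 0.1, 0.1, 0.54, 0.24 and 0.13, and the BCL-2 family median of 0.17 turned to -0.06 under upper-quartile scaling and -0.18 on the TPM scale. Interferon-stimulated genes had 4 higher and 8 lower of 14, p53 targets 7 and 5 of 14 with Sesn1 at -3.31 ± 0.04, and Foxp3 cofactors 13 and 10 of 23 with Stat5a at 2.15 ± 0.04, without a call. The medians of the p53 targets and the cofactors, 0.10 and 0.35, turned to -0.29 and -0.07 on the TPM scale. The mean of the p53 targets was -0.16, and the camera direction of the interferon-stimulated list was up against a median of -0.30. CD8 markers had 1 lower of 2, NK markers 1 higher of 2, myeloid markers 2 higher and 2 lower of 6, erythroid markers 1 lower of 3 and stromal markers 1 lower of 3, without a call. For the myeloid list the camera direction was down against a median of 0.58.

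Among genes with a mean log2 CPM of at least 3, the largest falls in control-guide cells were those of Rflnb at -5.97 ± 0.21, the cell cycle phosphatase gene Cdc25b at -5.34 ± 0.062, Pimreg at -5.24 ± 0.23, Depdc1b at -5.00 ± 0.28 and Tsc22d3 (GILZ) at -4.87 ± 0.067. They were followed by Kctd12b at -4.57 ± 0.11, St8sia1 at -4.49 ± 0.064, the thyroid hormone receptor gene Thra at -4.43 ± 0.09, Mxd3 at -4.39 ± 0.18 and the phosphodiesterase gene Pde2a at -4.37 ± 0.057. In all, 13620 genes were called, 6808 higher and 6812 lower, with 3636 higher and 4026 lower at 2-fold or more. Upper-quartile scaling moved the median of all genes from -0.01 to -0.246, and the log2(TPM+1) scale moved it to -0.197; 50% of calls were higher under TMM scaling and 37.2% on the TPM scale, and 47.5% and 34.6% of those at 2-fold or more.

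The fourth comparison made the same contrast in Foxp3-guide cells. Each list with a call with both guides moved in the same direction, and 5 of 14 cytokine genes rose more with the Foxp3 guide when the difference itself was tested. Olr1, Il1a and Idi2 were at 0 counts at 0 h and were at least 3550-fold, 1180-fold and 1160-fold higher at 3 h, against 3 counts over the group. Il3 rose by 14.98 ± 0.75, Ccl1 by 14.25 ± 0.97, Xcl1 by 13.85 ± 0.88, Ccl4 by 13.73 ± 0.53, Ccl3 by 13.32 ± 0.51 and Il2 by 13.27 ± 0.26. Il31 had 2 counts at 0 h and 21840 at 3 h, a log2 ratio of 13.51 with a counting interval of 11.66 to 16.56. All 14 cytokines rose, Il13 by 13.01 ± 0.47 and Csf2 by 11.62 ± 0.3, with a median of 9.35 (camera adjusted p = 1.1e-29; adjusted p = 0.031 with an estimated correlation). All 9 chemokines rose, with a fitted median of 10.57 and of 8.58 with the gene at 0 counts set to its bound (camera adjusted p = 5.1e-11; adjusted p = 0.079 with an estimated correlation).

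Immediate early genes had 20 higher and 2 lower of 22 in Foxp3-guide cells, led by Egr2 at 11.81 ± 0.17 and Nr4a3 at 9.62 ± 0.08, all 15 NF-kappaB targets rose, led by Nfkbid at 5.66 ± 0.04, and all 18 ribosome biogenesis genes rose, led by Polr1b at 5.55 ± 0.05. Their camera adjusted p values were 1.2e-28, 1.8e-17 and 2.1e-31, and each was 0.031 with an estimated correlation. Helper lineage factors had 10 higher and 3 lower of 13, costimulatory genes 10 and 2 of 12, IL-2 and STAT5 targets 9 and 2 of 12, and Treg signature genes 19 and 8 of 30. Examples were Zeb2 at 10.20 ± 0.3, Tnfsf14 at 8.20 ± 0.07, Lif at 7.49 ± 0.06 and Cd83 at 6.95 ± 0.1; these 4 lists also stood at an adjusted p of 0.031 with an estimated correlation. Inhibitory receptors had 9 higher and 1 lower of 10, led by Havcr2 at 9.01 ± 0.17 (camera adjusted p = 3.5e-09; adjusted p = 0.041 with an estimated correlation). Cell cycle genes had 19 lower and 1 higher of 20, with Ccnb2 at -2.83 ± 0.06 (camera adjusted p = 1.9e-07; adjusted p = 0.031 with an estimated correlation).

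Calls lost with an estimated correlation covered conventional T cell genes (11 lower and 4 higher of 15, Tcf7 at -4.73 ± 0.04; adjusted p = 0.097 with an estimated correlation) and homing genes (10 lower and 5 higher of 17, Cxcr4 at -4.30 ± 0.06; adjusted p = 0.056). They also covered cytotoxic genes (6 higher and 1 lower of 9, Serpinb6b at 4.46 ± 0.06; adjusted p = 0.097), glycolysis genes (14 and 1 of 16, Hk2 at 6.86 ± 0.09; adjusted p = 0.28) and cholesterol genes (12 and 4 of 16, Idi1 at 3.04 ± 0.05; adjusted p = 0.069). Amino acid stress genes (12 and 4 of 16, Chac1 at 5.90 ± 0.44; adjusted p = 0.069) and BCL-2 family genes (5 and 4 of 12, Bcl2l1 at 5.71 ± 0.05; adjusted p = 0.18) lost theirs as well, as did the chemokines above. The BCL-2 family call was also lost without either control-guide 3 h replicate (camera adjusted p = 0.17 and 0.16), and its median of 0.05 turned to -0.12 under upper-quartile scaling and -0.22 on the TPM scale. Lists without a call were respiratory chain genes (12 higher and 3 lower of 17), interferon-stimulated genes (5 and 6 of 14), p53 targets (5 and 7 of 14), Foxp3 cofactors (15 and 8 of 23) and the marker lists of B (1 and 4 of 5), CD8 (none of 2), NK (1 and 1 of 2), myeloid (2 and 1 of 6), erythroid (1 and 0 of 3) and stromal cells (1 and 1 of 3). The interferon-stimulated list had a median of -0.22 and a mean of 0.05, and the erythroid list 0.07 and -0.05. The CD8 and erythroid medians, 0.16 and 0.07, turned to -0.01 and -0.10 under upper-quartile scaling.

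At the same minimum level, the largest falls in Foxp3-guide cells were those of Kctd12b at -7.38 ± 0.43, Rflnb at -6.77 ± 0.19, S1pr1 at -6.61 ± 0.053, St8sia1 at -6.48 ± 0.066, Depdc1b at -6.31 ± 0.14 and Mettl7a1 at -6.31 ± 0.2. Klf2 (ENSMUSG00000055148.7; chromosome 8, 72319033 to 72321656) changed by -6.23 ± 0.087, Mturn by -6.11 ± 0.1, Tbx6 by -5.90 ± 0.24 and Nacc2 by -5.87 ± 0.24. The test called 14208 genes, 6794 higher and 7414 lower, and 3759 higher and 4725 lower at 2-fold or more. Of all calls 47.8% were higher under TMM scaling and 38.7% on the log2(TPM+1) scale. Upper-quartile scaling and the log2(TPM+1) scale moved the median of all genes from -0.068 to -0.242 and -0.177. TCR responses with the 2 guides, which share no library, correlated across genes with Pearson's r = 0.899 and Spearman's rho = 0.918. Of 12612 genes called with both guides, 96.6% had the same direction: 5973 were higher with both (2779 for independent lists) and 6214 lower with both (3035), while 425 were opposite.

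The last comparison tested whether the TCR response differed between the guides, which is the same as asking whether the guide effect differed between 3 h and 0 h. Positive values mean a more positive TCR change in Foxp3-guide cells. IL-2 and STAT5 targets had a more positive response in 10 of 12 cases and a more negative one in 1, including Cish at 2.14 ± 0.06, Ccnd2 at 1.44 ± 0.06, Il2ra at 1.41 ± 0.06 and Socs1 at 1.36 ± 0.1. Cish stood at 378.3 ± 0.0937 and 75.5 ± 1.16 CPM with control and Foxp3 guide at 0 h, and at 1100.0 ± 30.9 and 967.2 ± 8.76 CPM at 3 h. This list, with a median of 0.74, was the only one of 28 whose call held when the correlation was estimated (camera adjusted p = 3e-15; adjusted p = 0.027 with an estimated correlation).

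Other lists in this test had mixed or less certain differences. Treg signature genes had 15 higher and 8 lower of 30, with Itgb8 at 2.33 ± 0.1, Tnfrsf9 at 2.05 ± 0.06 and Cd83 at 1.94 ± 0.11 (camera adjusted p = 4.2e-05; adjusted p = 0.076 with an estimated correlation). Costimulatory genes had 6 higher and 4 lower of 12, with Tnfsf8 at 2.75 ± 0.06 and Tnfsf14 at -2.12 ± 0.2 (camera adjusted p = 9.9e-07; adjusted p = 0.076 with an estimated correlation). Homing genes had 6 higher and 7 lower of 17, with Ccr8 at -2.29 ± 0.06 and S1pr1 at -2.28 ± 0.07, and a median of -0.08 that turned to 0.06 on the log2(TPM+1) scale (camera adjusted p = 0.00017; adjusted p = 0.076 with an estimated correlation). Conventional T cell genes had 7 lower and 5 higher of 15, with Tcf7 at -2.10 ± 0.06 and Ccr7 at -1.57 ± 0.06 (camera adjusted p = 0.00019; adjusted p = 0.11 with an estimated correlation). Ribosome biogenesis genes had 12 higher and 2 lower of 18, led by Polr1b at 1.2 ± 0.07 (camera adjusted p = 1.4e-05; adjusted p = 0.21 with an estimated correlation). Cytotoxic genes had 3 higher and 3 lower of 9, with Serpinb6b at 2.67 ± 0.09 (camera adjusted p = 0.0049; adjusted p = 0.21 with an estimated correlation).

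Effector cytokines had 5 higher, none lower and 9 not past of 14, with Tnf at 2.16 ± 0.1 and Il17f at 1.84 ± 0.4; 3 members had a group at 0 counts, so their differences are not measured. The list's camera adjusted p of 0.044 rose to 0.099 without control-guide 0 h replicate 2 and to 0.51 with an estimated correlation. Leaving out control-guide 0 h replicate 1, control-guide 3 h replicate 1, Foxp3-guide 0 h replicate 1 or either Foxp3-guide 3 h replicate also ended this call, at 0.052, 0.054, 0.061, 0.062 and 0.06. Glycolysis genes had 11 lower and 3 higher of 16, with Tpi1 at -0.99 ± 0.06 and Hk2 at 1.44 ± 0.11 (camera adjusted p = 0.033; adjusted p = 0.51 with an estimated correlation). Their call ended without replicate 1 of the control guide at 0 h, the Foxp3 guide at 0 h or the Foxp3 guide at 3 h, at 0.07, 0.061 and 0.12. Stromal markers had 2 higher of 3, with Pecam1 at 1.11 ± 0.06 (camera adjusted p = 0.033; adjusted p = 0.21 with an estimated correlation; 0.054 without control-guide 3 h replicate 1). No call was made for the other 18 lists, among them cell cycle genes (6 higher, 5 lower and 9 not past of 20) and immediate early genes (11 higher and 5 lower of 22, Myc at 2.25 ± 0.07). Helper lineage factors had 4 higher and 6 lower of 13, with Tbx21 at -2.36 ± 0.14. Inhibitory receptors had 6 higher and 1 lower of 10 (Cd160 at 2.32 ± 0.26), NF-kappaB targets 6 and 4 of 15, chemokines 2 and 1 of 9, interferon-stimulated genes 4 and 4 of 14 and cholesterol genes 8 and 2 of 16. Respiratory chain genes had 11 lower and none higher of 17, amino acid stress genes 8 higher and 3 lower of 16, p53 targets 1 and 5 of 14, BCL-2 family genes 4 and 5 of 12 and Foxp3 cofactors 12 and 8 of 23. The B, CD8, NK, myeloid and erythroid marker lists had 2, 1, 0, 1 and 1 higher and 0, 0, 1, 1 and 0 lower. Median and mean differed in sign for chemokines (-0.09 and 0.06, with 2 of 9 members at 0 counts in a group; 0.14 as the median on the log2(TPM+1) scale) and BCL-2 family genes (-0.26 and 0.01), and the camera direction of the myeloid list was up against a median of -0.51.

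Single genes with large positive differences, among those with a mean log2 CPM of at least 3, were Ccn4 at 3.67 ± 0.3, Crtam at 3.56 ± 0.45, the adhesion gene Jaml at 3.45 ± 0.068, Pdzk1ip1 at 3.33 ± 0.59, the immune receptor gene Slamf7 at 3.17 ± 0.33, Samd4 at 2.94 ± 0.31 and Stc2 at 2.91 ± 0.14. Olr1, Sphk1 and Utf1 passed the same rule on few counts at 0 h. Olr1 had 6 and 2323 counts at 0 h and 3 h with the control guide and 0 and 9964 with the Foxp3 guide, Sphk1 had 3 and 2736 against 2 and 17413, and Utf1 had 8 and 2509 against 1 and 2866. Their calls ended without control-guide 0 h replicate 2 (Olr1, adjusted p = 1), control-guide 0 h replicate 1 (Sphk1, 0.316) and Foxp3-guide 0 h replicate 1 (Utf1, 0.173). That of Sphk1 ended also without control-guide 0 h replicate 2 (0.05) or Foxp3-guide 0 h replicate 1 (0.077) or 2 (0.0702), and that of Utf1 without control-guide 0 h replicate 1 (0.0601). The largest negative differences at this level were those of Vipr1, a neuropeptide receptor gene, at -3.54 ± 0.14, Npas4 at -3.49 ± 0.32, the chemokine receptor gene Cx3cr1 at -3.29 ± 0.12, Apol9b at -2.82 ± 0.12 and Slc14a1 at -2.68 ± 0.1. Klf2, Hmgb1-ps8, Mmp11 and Gadd45g followed at -2.53 ± 0.1, -2.48 ± 0.2, -2.47 ± 0.23 and -2.42 ± 0.15. Kctd12b stood at -2.81 ± 0.45, a value that turned to 1.36 on the log2(TPM+1) scale. Mmp11 was -0.35 there and no longer past the threshold, and the difference of Utf1 turned negative there.

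**Figure D3:**
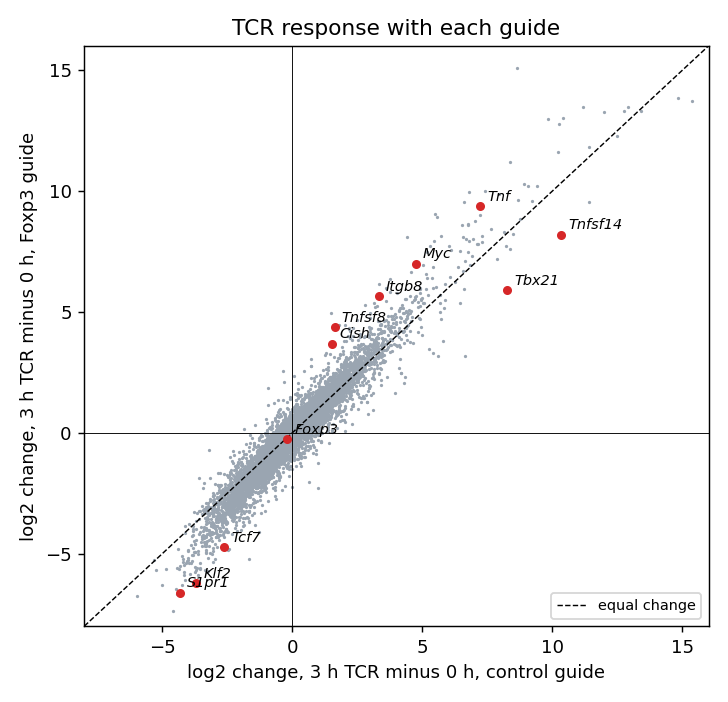
Log2 change after 3 h of TCR stimulation in control-guide cells (horizontal) and Foxp3-guide cells (vertical) for the 9622 genes with a mean log2 CPM of at least 3; the dashed line marks equal changes. Klf2 and S1pr1 lie below the line and Tnf, Myc and Tnfsf8 above it.

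The interaction test called 7457 genes, 2960 with a more positive TCR change in Foxp3-guide cells and 4497 with a more negative one, and 555 and 1002 at 2-fold or more. The share of positive calls was 39.7% under TMM scaling, 48.7% under median-ratio and upper-quartile scaling, 51.3% on the log2(TPM+1) scale and 53.2% without Foxp3-guide 3 h replicate 1. At 2-fold or more it was 35.6% under TMM scaling and 47.5% on the log2(TPM+1) scale. Among 3054 genes that rose at least 2-fold with both guides, 1371 differed between them, 967 with the larger rise in Foxp3-guide cells and 404 with the smaller. Among 3613 genes that fell at least 2-fold with both, 1669 differed, 1456 with the larger fall in Foxp3-guide cells and 213 with the smaller. Over all tested genes the SD of the TCR log2 changes was 1.15 times as large with the Foxp3 guide as with the control guide.

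Guide effects were also set against the TCR response of control-guide cells, with which they share libraries. At 0 h the correlation across genes was 0.043 and the covariance 0.079, beside a covariance of 0.066 in 10 simulated draws with no effect, a difference of 0.013. In all, 2491 genes were higher in both and 2323 lower in both, where independent lists would give 2329 and 1983, while 4285 had opposite directions (2379 higher with the Foxp3 guide and lower with TCR stimulation, 1906 the reverse, against 2331 and 1982). The covariance at 0 h turned to -0.0898 among genes with a mean log2 CPM of at least 3 and was 0.295 or 0.325 without control-guide 0 h replicate 1 or 2 and 0.00792 without Foxp3-guide 0 h replicate 2. At 3 h the correlation was 0.1 and the covariance 0.188, beside -0.0714 simulated, a difference of 0.259. Here 2808 genes were higher in both and 2856 lower in both (2088 and 2099 for independent lists), while 3236 had opposite directions (1608 and 1628, against 2089 and 2097). Without control-guide 3 h replicate 1 or 2 the covariance was -0.0227 or 0.0223. The simulated draws gave every library the mean of the shared control group, so genes at 0 counts there carried no noise. The controls were not split, since each part would hold 1 library. Leaving out 1 control library moved the covariance at 0 h by far more than the difference of 0.013. All or part of that difference may come from the shared controls. At 3 h the shared libraries enter the 2 effects with opposite signs, and the simulated covariance was negative.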

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

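The 2-fold test of the interaction, the use of planned scalings and of other tests on the cell cycle and alpha globin patterns, and the reading of culture differences were chosen only after the results were seen, and thinning was chosen after the depths were seen. Single genes and lists stand out here because the guide effect differed between 0 h and 3 h; the wider spread of TCR changes, the cell cycle genes and the alpha globin genes are weighed as patterns noticed in the results. For single genes the difference was tested against 2-fold: 29 of 70 named genes passed, and 537 of all tested genes, 210 higher and 327 lower at 3 h. The named genes include those picked for the largest called differences in the interaction, from the same data. Their share was raised by that choice and cannot be set against the share of all genes. Olr1 passed as well but is left out because a group had 0 counts.

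Genes whose estimated guide effect was negative at 0 h and positive at 3 h were Ccn4 (difference 3.67), Crtam (3.56), Jaml (3.45), Pdzk1ip1 (3.33), Slamf7 (3.17) and Samd4 (2.94). Vipr1 (-3.54), Npas4 (-3.49), Cx3cr1 (-3.29), Gadd45g (-2.42), S1pr1 (-2.28), Mettl7a1 (-2.07) and St8sia1 (-1.99) went from positive to negative. Itgb8 (2.33) and Cd83 (1.94) were lowered less at 3 h than at 0 h. Prr5l (-2.23) and Tnfsf14 (-2.12) were raised less at 3 h, and F2rl2 (2.48) and Stc2 (2.91) had the more positive value at 3 h. Apol9b (-2.82), Kctd12b (-2.81), Slc14a1 (-2.68), Klf2 (-2.53), Hmgb1-ps8 (-2.48), Mmp11 (-2.47), Tbx6 (-2.28), Mturn (-1.97), Myb (-1.47) and Pde2a (-1.26) were lowered more at 3 h; on the log2(TPM+1) scale the difference of Kctd12b turned to 1.36 and that of Mmp11 was -0.35 and no longer past the threshold.

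Among lists, the median difference was 0.22 for the Treg signature, -0.35 for conventional T cell genes, 1.45 for effector cytokines, 0.43 for costimulatory genes, -0.08 for homing genes, 0.74 for IL-2 and STAT5 targets, 0.31 for cytotoxic genes, 0.29 for ribosome biogenesis genes, -0.34 for glycolysis genes and 1.11 for stromal markers. The cytokine median is no firm value, since 3 of 14 members, Il3, Il9 and Il22 (named after their values were seen), had a group at 0 counts and no measurable difference, and Il22 and Il21 (SE 1.8) set the median. The homing median turned to 0.06 on the log2(TPM+1) scale. Only the IL-2 and STAT5 list kept its call with an estimated correlation.

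TCR log2 changes were spread more widely with the Foxp3 guide. Among genes with a mean log2 CPM of at least 3 the SD ratio was 1.14, thinning to equal totals left 1.15 (1.17 over all tested genes), and the lowest over the ways of taking 1 library per group was 1.14. Genes with a mean log2 CPM of at least 6 gave 1.12, and over all tested genes the lowest ratio with a single library left out was 1.1, without control-guide 0 h replicate 2. These values argue against depth, genes near the detection floor and a single deviating library as the whole cause. Culture or plate differences between the guides cannot be told apart from the guide (ratio 1.14 at the minimum of 3), because the labels give no batch. A wider response without Foxp3 is a hypothesis that no test here decides.

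Cell cycle genes were higher with the Foxp3 guide at both times. The lower of the list medians was 2.23 after thinning and 2.16 over the RLE and upper-quartile scalings, which argues against depth and scaling. Among 11 markers of CD8, B, NK and myeloid cells, picked after the results were seen, the highest in a Foxp3-guide group was Cd8b1 at 3.6% of Cd4 (3.7% in control-guide cells at 3 h), which argues against dividing cells of those lineages as the whole cause. Outside that set, Ighm stood at 250.2 CPM with the Foxp3 guide at 0 h, lower than the 926.3 CPM with the control guide, and the NK gene Klrb1c had 147 against 3 counts, so a few such cells stay open. Conventional CD4 T cells, which the sort for reporter-positive cells before culture would remove, and culture differences were not tested and stay open. Faster division without Foxp3 is likewise an untested hypothesis.

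Alpha globin transcripts were higher with the Foxp3 guide. Beta globin counts were 0.75% of alpha globin counts (160 against 21333), which argues against red cell RNA, and the summed alpha globin counts rose by at least 2.99 on the log2 scale, which argues against a different division of reads between the copies. No biological explanation was tested.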

How the results depend on the processing

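Thinning was chosen only after the data were seen; the other alternatives were planned. Counts of changed genes stayed within 1.5 times the reported count except under stricter rules, which by construction call fewer genes. A similar count did not mean the same genes. On the log2(TPM+1) scale, 7558 of 10539 calls at 0 h and 7142 of 10231 at 3 h recurred in the same direction. For the interaction 4722 of 7457 did, and for the TCR effects 11605 of 13620 and 12306 of 14208. A 2-fold minimum gave 2586 and 2760 genes for the guide effects at 0 h and 3 h, 7662 and 8484 for the TCR effects with control and Foxp3 guide, and 1557 for the interaction. A test against 1.2-fold gave 6418, 6039 and 3963 for the guide effects and the interaction. With single libraries left out the counts ran from 9375 to 10744, 8882 to 10253, 12970 to 13582, 13451 to 14265 and 6553 to 7323 in the 5 comparisons; a library left alone in its group is assumed to vary like the other groups.

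List calls depended on whether the correlation was preset or estimated. Some lists lost their call although the estimated correlation lay below the preset 0.01. Examples were NF-kappaB targets at 0 h (0.004) and homing genes at 3 h (-0.0078). Calls that held were also much weaker. Cell cycle genes at 0 h, with an estimated correlation of -0.023, went from a camera adjusted p of 2.5e-66 to 0.0012. IL-2 and STAT5 targets in the interaction (0.00034) went from 3e-15 to 0.027. A higher correlation does not account for these changes, whose cause was not tested. The loss of a call with an estimated correlation therefore cannot be read as an effect of correlation between genes. With an estimated correlation 4, 3, 11, 10 and 1 lists passed in the 5 comparisons, against 10, 11, 20, 18 and 10. The fry test gave 23, 26 and 24 for the guide effects at 0 h and 3 h and the interaction. It sets a list against no change, and camera sets it against the other genes, so the fry counts are not an effect of the correlation. Leaving out single libraries gave 10 to 10, 11 to 14, 20 to 20, 17 to 18 and 8 to 11. No list reversed.

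The correlation of guide effects between 0 h and 3 h, 0.556, was 0.534 after thinning, 0.671 among genes with a mean log2 CPM of at least 3, and 0.51 to 0.532 with single libraries left out. That of the TCR effects, 0.899, was 0.961 among those genes and 0.879 to 0.893. The covariance of guide effect and control-guide TCR effect at 0 h was -0.0898 among those genes and 0.00792 to 0.325 with single libraries left out; at 3 h it was -0.0227 (without control-guide 3 h replicate 1) to 0.22. The cause was not tested. The SD ratio of TCR effects was 1.1 to 1.18.

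Reversed single genes were Eomes in the guide effect at 0 h (-0.01 on the log2(TPM+1) scale with or without the filter, -0.02 on log2(TPM+0.1)), Atp5b at 3 h (-0.07 on all 3), Hba-a1 in the TCR effect with the Foxp3 guide (-0.04 under upper-quartile scaling, -0.16 on the 3 TPM scales), and, for the interaction on log2(TPM+1) with or without the filter, Utf1 (-0.40) and Kctd12b (1.36); the cause was not tested. Over all named genes and alternatives, calls were lost in 33, 38, 7, 20 and 66 cases. The outcome was unchanged in 2182, 2335, 2205, 2185 and 2119. A case also counted as unchanged where neither setting called the gene, as for Foxp3 in the interaction, or where DESeq2 gave no adjusted p. Replicate numbers do not pair the libraries: correlations of paired residuals ran from -0.0757 to 0.00947. After thinning, 10206, 9652, 13461, 13698 and 6880 genes were called, so fewer in each comparison at the lower depth.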
